A study of Cereibacter sphaeroides 2.4.1 with 12 samples.

How the data were processed

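Total RNA from the photosynthetic bacterium Rhodobacter sphaeroides 2.4.1 (now Cereibacter sphaeroides) and from an nnrR mutant of it was measured on oligonucleotide arrays. NnrR is known as a transcription regulator of the response to nitric oxide. Per the labels, cultures grew semiaerobically in minimal medium with succinate. RNA was taken before any addition and 15 min after 1 mM S-nitrosoglutathione (GSNO) or 1 mM sodium nitroprusside (SNP), both of which are nitrosating reagents. No culture without reagent was sampled at 15 min. A change against untreated, called a response below, therefore also holds 15 min of time and handling. The 12 arrays form 6 groups of 2, and the labels call the 2 arrays of a group separate cultures.

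The deposited values are array signals on a linear intensity scale, 1 per probe set and array. How the authors summarised probes into these values is not given in the sources used here. After the lowest and highest 2 percent of an array's values were left out, its mean lay between 498.6 and 499.1 on all 12 arrays. The deposited values had therefore been scaled per array. The median signal of the arrays ranged from 180.2 to 220.6. The number of arrays limits the precision, and the self-test below shows what it allows if probe sets vary independently.

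Of 5355 probe sets, 3 that detect the control transcript thrC were left out and 5352 were tested. The platform annotation given for this work pairs 539 of the tested probe sets with 1 gene symbol, none with several, and leaves 4813 without a symbol. These 539 probe sets carry 498 distinct symbols and 514 Entrez gene identifiers. Of the symbols, 494 were found in the RefSeq gene table of strain 2.4.1, which was used only for the order of the genes. No coordinates are printed, since the build behind the arrays is not given in the sources used here. The names nnrR and nor do not occur among the 539, so the mutated gene could not be looked up on the arrays and the strain labels were not checked in this way.

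Values were transformed as log2(signal + 23.8), where 23.8 is the 10th percentile of the table, so the log2 change of a dim probe set is understated. A model with 1 mean per group was fitted to all 12 arrays with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with 6 residual and 3.915 prior degrees of freedom. The 9 contrasts were each reagent against untreated in each strain, the untreated strains against each other, the difference between the strains in each reagent's effect, and SNP against GSNO in each strain. P-values are 2-sided, with Benjamini-Hochberg adjustment over the 5352 probe sets and a threshold of 0.05. Errors of log2 changes are standard errors from this fit, and errors of signals are SDs over 2 arrays.

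For gene groups, 24 lists were fixed from textbook knowledge before the data were examined, and matched by symbol. Counts of list members therefore cover only genes with a symbol. The list of nitric oxide reductase and nitric oxide response and that of periplasmic nitrate reductase had no member. Of the others, 18 held at least 3 genes and were tested with camera of limma (preset correlation 0.01, adjusted over the 18 lists), and 4 held 1 or 2 genes. Each gene entered with its probe set of highest mean. Genes were first told apart by symbol, which merged paralogs of bfr, groEL, atpA, atpD, sdhA, fumC and cysE. This was changed to Entrez identifiers after the first list results had been seen. No list was past the threshold with an estimated correlation in any of the 9 contrasts, so that adjusted p is given beside each list called with the preset one.

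The rule for named genes, also set before the data were examined, took the 10 largest rises and 10 largest falls past the threshold whose arrays did not overlap between groups, the 10 largest differences for the other contrasts, and up to 4 members of each list. It fell back on locus tags for genes without a symbol, which the annotation does not give. It was therefore applied to the 539 probe sets with a symbol, a narrowing decided after the annotation was seen and before any fit. Taken over all probe sets, 0 to 2 of each 10 had a symbol. Gene symbols are printed as the annotation gives them.

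The method was tested on simulated data for the wild type GSNO comparison. Of 100 probe sets changed by 1 on the log2 scale 43% were recovered, and of 100 changed by 2, 93%. Of 143 calls in all, 7 were false. The simulated noise was drawn independently for each probe set and array. A deviation shared by many probe sets of a culture was therefore not simulated, and its effect on these shares was not tested. For the correlation and covariance of responses that share untreated arrays, 100 simulations of unchanged groups were run. The alternatives were quantile normalization, median centring, other pseudocounts, leaving out the dimmest 25% of probe sets, an intensity trend, only the arrays of the groups compared, the replicate number as a block, and leaving out each array. Scaling to the thrC control was added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.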

Results

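The study measured how Rhodobacter sphaeroides 2.4.1 and an nnrR mutant changed their transcript levels within 15 min of 1 mM GSNO or SNP. Each of the 6 groups held 2 arrays, whose log2 values correlated across probe sets with Pearson's r between 0.959 and 0.977. Probe sets are not independent replicates. The p-values rest on the spread between 2 cultures per group, pooled over all groups.

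In the wild type with GSNO, 4 of 5 genes for iron uptake and storage, 2 of 3 for iron-sulfur cluster assembly, metF and metZ rose. Those that fell were cysT, cysW and the 3 genes with a symbol of the cbb3 terminal oxidase. For these 3 lists the adjusted p = 0.138, adjusted p = 0.138 and adjusted p = 0.217 with an estimated correlation. The largest rise among genes with a symbol was that of metF, which encodes methylenetetrahydrofolate reductase: its signal went from 1049 ± 9.12 to 17241 ± 633 (SD, n = 2), a log2 change of 4.01 ± 0.18. The gene glpD, for glycerol-3-phosphate dehydrogenase, rose by 3.97 ± 0.18 on the log2 scale. The largest fall was that of cysT, a subunit of the sulfate permease, at -2.78 ± 0.33, and its partner cysW changed by -1.87 ± 0.26. The gene metZ, of the step that adds sulfide in methionine synthesis, rose by 2.24 ± 0.27.

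Among the 5 genes for iron uptake and storage, 4 rose and 1 fell, and the counts adjusted over the list alone were also 4 and 1. The risers were exbB and exbD (log2 changes of 3.41 ± 0.35 and 2.81 ± 0.34), which power uptake through the outer membrane, feoB (2.42 ± 0.18), the ferrous iron transporter, and a bacterioferritin gene, bfr of probe set 2452 (2.61 ± 0.20). The camera adjusted p was 7.3e-05, and the adjusted p = 0.138 with an estimated correlation. Of 3 genes for iron-sulfur cluster assembly, SufC and sufB rose, by 2.26 ± 0.17 and 2.01 ± 0.20, and the third, nifS, did not pass; adjusted over the list alone the count was 2. Its adjusted p was 0.00019, and adjusted p = 0.138 with an estimated correlation. The cbb3 oxidase reduces oxygen at low oxygen levels. All 3 of its genes with a symbol fell: ccoP by 2.38 ± 0.30, ccoO by 2.29 ± 0.30 and ccoN by 1.73 ± 0.21. Adjusted over the list alone the count was 3, the adjusted p 0.00019, and adjusted p = 0.217 with an estimated correlation.

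Of 9 genes of sulfur assimilation, cysteine and methionine, 3 rose and 2 fell in the wild type with GSNO (adjusted over the list alone, 5 and 2). The list's median change was 0.55, with adjusted p 0.0228, and adjusted p = 0.327 with an estimated correlation. Of 8 heme synthesis genes 2 rose, hemF by 1.61 ± 0.30 and hemN by 0.82 ± 0.22, the coproporphyrinogen oxidases that work with and without oxygen, and 2 also rose adjusted over the list alone. That list had adjusted p 0.0286, and adjusted p = 0.459 with an estimated correlation. Of 20 flagellar and chemotaxis genes, fliN (-1.91 ± 0.29) and fliG (-1.32 ± 0.34), both of the rotor switch, fell, and adjusted over the list alone 4 did. The list's median was -0.51, its adjusted p 0.00466, and adjusted p = 0.459 with an estimated correlation. Of 17 DNA repair genes, recA, the recombinase of the SOS response, and lexA, its repressor, rose by 1.51 ± 0.23 and 1.56 ± 0.21, and adjusted over the list alone 3 were higher and 2 lower. The list did not pass, at adjusted p 0.148. The translation elongation factor gene fusA fell by 2.21 ± 0.32. One of 45 ribosomal protein genes fell, rpsP at -1.25 ± 0.30, and rimM, a factor of ribosome maturation, changed by -1.17 ± 0.24. The redox sensor gene appA (probe set 2474) rose by 1.65 ± 0.42, and msrA, for methionine sulfoxide reductase, by 0.87 ± 0.21.

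In total 471 of 5352 probe sets passed in this comparison by limma, 204 higher and 267 lower, and 49 of them had a symbol. Without 1 or the other untreated wild type array (replicate 1 or 2) 255 or 244 passed. The balance moved with scaling, to 255 higher and 192 lower after median centring and to 181 higher and 131 lower after scaling to the thrC control. When each of the 12 arrays was left out in turn, calls were lost for hemN in 12 fits, appA in 9, fliG in 8, msrA in 5, rpsP and rimM in 3 each, and hemF in 1. The highest adjusted p was 0.255 for hemN, 0.191 for appA, 0.209 for fliG, 0.167 for msrA and 0.0969 for rimM without the untreated replicate 1 array, 0.0619 for hemF without the untreated replicate 2 array, and 0.133 for rpsP without the GSNO replicate 2 array.

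With SNP in the wild type, 4 of 5 iron genes rose and the 3 oxidase genes fell, and hemT, cysT and cysW rose, while metF did not pass. For both lists the call was lost with an estimated correlation, at adjusted p = 0.0763 and adjusted p = 0.104. The gene hemT, for an isozyme of 5-aminolevulinate synthase, the entry to heme synthesis, went from a signal of 17.3 ± 11.3 to 8043 ± 1030 (SD, n = 2). The untreated level is below the pseudocount of 23.8, so no log2 change is given for it. The rise of glpD was 4.44 ± 0.18, and cysT and cysW rose by 2.69 ± 0.33 and 2.61 ± 0.26. The signal of metF was 996 ± 122 after SNP.

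The iron list had 4 higher and 1 lower in the wild type with SNP, again 4 and 1 adjusted over the list alone, with exbB at 3.15 ± 0.35, feoB at 2.99 ± 0.18, exbD at 2.88 ± 0.34 and bfr of probe set 2452 at 2.25 ± 0.20. The member that fell was a paralog, bfr of probe set 4296, at -0.84 ± 0.19. The list's adjusted p was 1.1e-06, and adjusted p = 0.0763 with an estimated correlation. SufC and sufB rose by 2.17 ± 0.17 and 1.92 ± 0.20, 2 of 3 genes of cluster assembly and 2 adjusted over the list alone, with adjusted p 7.6e-05 and adjusted p = 0.0763 with an estimated correlation. The 3 oxidase genes ccoN, ccoO and ccoP fell by 1.88 ± 0.21, 2.17 ± 0.30 and 1.91 ± 0.30, 3 also adjusted over the list alone, with adjusted p 2.0e-06 and adjusted p = 0.104 with an estimated correlation.

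None of the 45 ribosomal protein genes passed alone in the wild type with SNP, nor adjusted over the list alone, while their median was -0.84 and the list's adjusted p 1.8e-10; without either wild type GSNO array 5 passed. With an estimated correlation its adjusted p = 0.531. Bacteriochlorophyll synthesis (11 genes, median -0.54, adjusted p 0.00494) and carotenoid synthesis (4 genes, median -0.68, adjusted p 0.028) had 0 members past the threshold. Adjusted over the list alone 0 and 1 were lower, and with an estimated correlation their adjusted p = 0.581 and adjusted p = 0.527. Of the 20 flagellar genes fliE and fliG fell, by 2.38 ± 0.52 and 1.59 ± 0.34, and 3 adjusted over the list alone, with adjusted p 7.7e-06 and adjusted p = 0.306 with an estimated correlation. Heme synthesis had hemT and hemN (1.23 ± 0.22) past the threshold among 8 genes, with 3 higher adjusted over the list alone. Its median of -0.10 and its mean of 0.98 differ in sign, and the list did not pass, at adjusted p 0.186. Further falls were those of fusA (-1.90 ± 0.32), metK, the S-adenosylmethionine synthetase gene (-1.09 ± 0.22), and phoU, of phosphate signalling (-0.75 ± 0.17).

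In total 173 probe sets passed by limma, 134 higher and 39 lower, and 25 had a symbol; scaling to the thrC control gave 123 higher and 17 lower. The number lower was 20 and 16 without the untreated arrays of replicates 1 and 2, and 19 and 22 without the SNP arrays of replicates 1 and 2. Among the 12 fits without an array, calls were lost for bfr of probe set 4296 in 12, phoU in 10, fliG in 7, fliE in 6, hemN and metK in 3 each, and fusA in 2. The highest adjusted p was 0.332 for bfr and 0.252 for fliG without the SNP replicate 2 array, 0.205 for fliE without the SNP replicate 1 array, 0.115 for hemN without the untreated replicate 1 array, and 0.229, 0.192 and 0.0813 for phoU, metK and fusA without the untreated replicate 2 array.

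In the nnrR mutant with GSNO, 4 of 5 iron genes, 2 of 3 genes of iron-sulfur cluster assembly and metF rose, and the 3 oxidase genes and 37 of 45 ribosomal protein genes fell. With an estimated correlation the adjusted p = 0.188 for the first 3 lists and adjusted p = 0.291 for the ribosomal one. The signal of metF went from 1145 ± 109 to 25037 ± 2920 (SD, n = 2), a log2 change of 4.42 ± 0.18, and glpD rose by 4.56 ± 0.18. The gene dksA, for a regulator that binds RNA polymerase, fell by 3.12 ± 0.25, and cysT by 3.27 ± 0.33. Of the ribosomal protein genes 45 fell when adjusted over the list alone, with a median of -1.65.

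The ribosomal list had adjusted p 7.2e-20 in the mutant with GSNO, and adjusted p = 0.291 with an estimated correlation. Among its members rplF changed by -2.88 ± 0.46, rplR by -2.80 ± 0.39, rplQ by -2.57 ± 0.38 and rplV by -2.01 ± 0.33, and rpsH and rpsN by -2.91 ± 0.49 and -2.82 ± 0.47. Of the 45, 8 passed without the untreated mutant array of replicate 1 (median -1.51), 24 without that of replicate 2 (-1.81), and 10 without the GSNO mutant array of replicate 1 (-1.29). Of 8 genes of the tricarboxylic acid cycle 4 fell (5 adjusted over the list alone), among them mdh, for malate dehydrogenase, at -1.77 ± 0.29 and sucD, of succinyl-CoA synthetase, at -1.39 ± 0.24. That list had adjusted p 0.00493, and adjusted p = 0.188 with an estimated correlation, and without the replicate 1 array of either group 2 of the 8 passed. Of 4 genes of branched-chain amino acid synthesis leuB (-1.71 ± 0.32) and leuC (-0.88 ± 0.21) fell, 2 also adjusted over the list alone, with adjusted p 0.0141 and adjusted p = 0.188 with an estimated correlation. The 9 genes of NADH dehydrogenase had a median of -0.40 with 0 past the threshold and 2 lower adjusted over the list alone, adjusted p 0.0141 and adjusted p = 0.629 with an estimated correlation. The call of leuC was lost without the replicate 1 array of the untreated mutant (adjusted p 0.135) or of the GSNO mutant (0.125).

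Of 5 iron genes 4 rose in the mutant with GSNO, and 4 adjusted over the list alone: bfr of probe set 2452 by 3.38 ± 0.20, exbB by 2.56 ± 0.35, exbD by 2.20 ± 0.34 and feoB by 0.78 ± 0.18. The list had adjusted p 0.00264, and adjusted p = 0.188 with an estimated correlation. SufC and sufB rose by 2.32 ± 0.17 and 2.25 ± 0.20, 2 of 3 and 2 adjusted over the list alone, with the same 2 adjusted p values. The oxidase genes ccoN, ccoO and ccoP changed by -2.71 ± 0.21, -2.75 ± 0.30 and -2.71 ± 0.30, 3 lower also adjusted over the list alone, with adjusted p 0.00011 and adjusted p = 0.188 with an estimated correlation. Among genes of other lists, hemN fell by 1.95 ± 0.22 while hemF rose by 1.83 ± 0.30. The chaperonin gene groEL of probe set 3245 fell by 1.82 ± 0.22, clpA, of a protease, rose by 1.33 ± 0.22, and msrA by 1.33 ± 0.21. The SOS genes recA and lexA rose by 1.72 ± 0.23 and 1.15 ± 0.21. The ATP synthase gene atpD of probe set 3233 fell by 1.99 ± 0.28 and its paralog of probe set 4901 rose by 1.40 ± 0.25. Of the flagellar genes fliE (-2.87 ± 0.52) and fliN (-1.85 ± 0.29) fell and fliD, the filament cap, rose by 1.75 ± 0.31. The 5 probe sets of fnrL, the anaerobic regulator, rose, by between 2.22 and 2.38, and appA of probe set 2474 by 2.26 ± 0.42.

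In total 946 probe sets passed by limma, 450 higher and 496 lower, and 155 had a symbol. Without the untreated mutant array of replicate 1 the count was 388 and without the GSNO mutant array of replicate 1 it was 407, the number lower was 319 without the untreated array of replicate 2, while scaling to the thrC control gave 210 higher and 554 lower. The call of feoB was lost without the replicate 1 array of the untreated mutant (adjusted p 0.113) or of the GSNO mutant, and when scaled to the control (0.191), that of fliE without the GSNO replicate 1 array (0.0508), and that of lexA when scaled to the control (0.0827).

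In the mutant with SNP, hemT, glpD, cysT and cysW rose, and 10 of 11 genes of bacteriochlorophyll synthesis fell, or 2 without the replicate 1 array of either group. For this list adjusted p = 0.126 with an estimated correlation. The signal of hemT went from 19.6 ± 10.7, below the pseudocount, to 4436 ± 978 (SD, n = 2), and glpD rose by 4.90 ± 0.18. The uptake genes for glycerol 3-phosphate, ugpB and ugpA, rose by 2.83 ± 0.23 and 2.60 ± 0.26, and cysW and cysT by 2.58 ± 0.26 and 2.32 ± 0.33. The largest falls among genes with a symbol were those of hemN (-3.61 ± 0.22) and dksA (-3.57 ± 0.25).

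Of 11 genes of bacteriochlorophyll synthesis 10 fell in the mutant with SNP (11 adjusted over the list alone), with bchE, of the oxygen-independent ring cyclase, at -2.64 ± 0.32 and bchJ at -2.59 ± 0.32. The list's median was -1.73, its adjusted p 7.4e-16, and adjusted p = 0.126 with an estimated correlation. Of 4 carotenoid genes 2 fell (4 adjusted over the list alone), crtA by 1.67 ± 0.30 and crtB by 1.06 ± 0.21, with adjusted p 3.4e-05 and adjusted p = 0.166 with an estimated correlation. Of 7 genes of the photosynthetic complexes 2 fell (5 adjusted over the list alone), pucC by 2.17 ± 0.37 and pufQ by 1.94 ± 0.40, with adjusted p 3.7e-06 and adjusted p = 0.226 with an estimated correlation. Of 8 heme synthesis genes 3 fell and hemT rose (5 lower and 2 higher adjusted over the list alone), with hemA, another 5-aminolevulinate synthase, at -1.55 ± 0.27. That list's adjusted p was 0.0253, and adjusted p = 0.359 with an estimated correlation. Without the replicate 1 array of either the untreated or the SNP mutant, bacteriochlorophyll synthesis had 2 members past the threshold and the carotenoid and photosynthetic lists had 0; without the untreated replicate 2 array they had 6, 1 and 1. Without the SNP replicate 1 array the adjusted p was 0.114 for crtA, 0.169 for crtB, 0.0869 for pucC, 0.186 for pufQ and 0.0961 for hemA.

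The iron list had 3 of 5 genes higher in the mutant with SNP, 3 higher and 1 lower adjusted over the list alone: exbD (3.31 ± 0.34), exbB (3.28 ± 0.35) and bfr of probe set 2452 (2.63 ± 0.20). The list's adjusted p was 0.00225, and adjusted p = 0.193 with an estimated correlation. SufC and sufB rose by 2.14 ± 0.17 and 1.72 ± 0.20, 2 of 3 and 2 adjusted over the list alone, with adjusted p 4.7e-05 and adjusted p = 0.112 with an estimated correlation. The oxidase genes ccoN, ccoO and ccoP fell by 2.16 ± 0.21, 2.27 ± 0.30 and 2.09 ± 0.30, 3 also adjusted over the list alone, with adjusted p 1.9e-07 and adjusted p = 0.112 with an estimated correlation. Ribosomal proteins (45 genes, median -0.55) and flagella (20 genes, median -0.33) had 0 genes past the threshold and 0 adjusted over the list alone. Their adjusted p were 1.9e-08 and 0.00016, and with an estimated correlation adjusted p = 0.359 and adjusted p = 0.289. The genes fusA and metK fell by 2.21 ± 0.32 and 1.40 ± 0.22, the latter lost without the SNP replicate 1 array (adjusted p 0.0603).

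In total 268 probe sets passed by limma, 158 higher and 110 lower, and 51 had a symbol. The count was 116 without the SNP mutant array of replicate 1, and 158 and 178 without the untreated mutant arrays of replicates 1 and 2, and the balance was 133 higher and 142 lower after median centring and 202 higher and 73 lower when scaled to the thrC control.

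**Figure D1:**
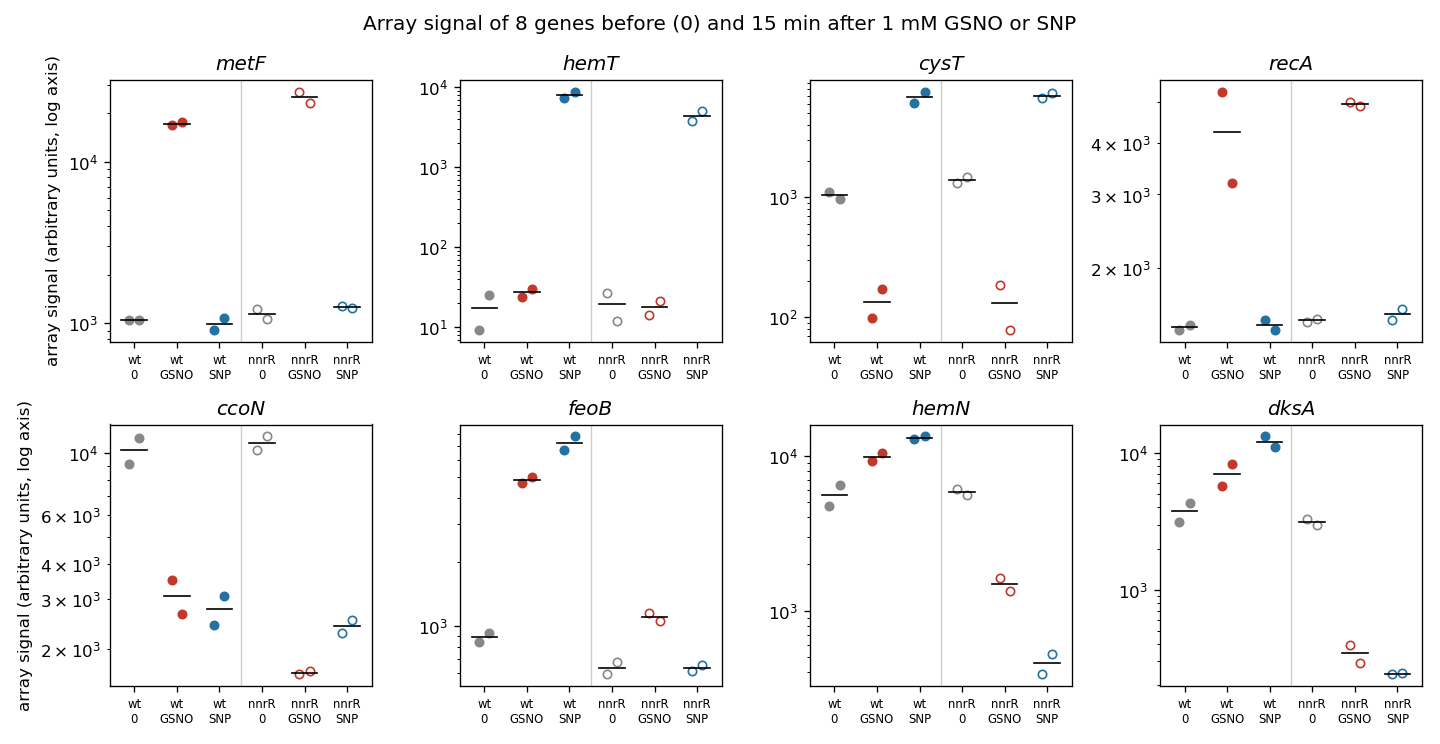
Array signal (arbitrary units, log axis) of 8 genes on all 12 arrays, by strain (filled, wild type; open, nnrR mutant) and reagent, with 0 for untreated; points are single arrays and lines are means of 2. The mean hemT signal is 8043 and 4436 in the 2 SNP groups and under 28 elsewhere, and dksA, hemN and feoB are lower in the treated mutant than in the treated wild type.

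Before any reagent, 0 of 5352 probe sets differed between the strains past the threshold by limma, with 296 at an unadjusted p under 0.05, where chance gives 267.6. The simulation, run for the wild type GSNO comparison, which also sets 2 arrays against 2, recovered 43% of changes of 1 on the log2 scale, so differences of that size are not excluded. It held many changed probe sets. Where few truly differ the adjustment is stricter, so recovery may be lower here and larger differences are not excluded either. The smallest adjusted p, 0.0696, was that of probe set 1354, which has no symbol and had a log2 difference of 1.47 ± 0.18, and whose response to both reagents also differed between the strains. Among the genes with a symbol that later differed, dksA was at 3741 ± 834 in the untreated wild type and 3150 ± 234 in the untreated mutant (SD, n = 2), and hemN at 5597 ± 1207 and 5800 ± 380. The signal of feoB was 885 ± 63.1 and 634 ± 59.2, a log2 difference of -0.47 ± 0.18 that did not pass. Of the lists, ribosomal proteins (median 0.24, adjusted p 0.00104) and NADH dehydrogenase (median 0.26, adjusted p 0.0108) were higher in the mutant, with 0 of 45 and 0 of 9 genes past the threshold and 0 adjusted over the list alone. With an estimated correlation adjusted p = 0.775 for both, and the ribosomal median was -0.11 under 1 other scaling.

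The responses to the reagents differed between the strains for 3 genes with a symbol, and for the same 3 with each reagent. Both tests use the same untreated arrays of both strains, so their agreement is in part built in. The effect of GSNO on dksA was lower in the mutant than in the wild type by a log2 difference of -4.02 ± 0.35, on hemN by -2.77 ± 0.32 and on feoB by -1.64 ± 0.25. With SNP the differences were -5.27 ± 0.35 for dksA, -4.84 ± 0.32 for hemN and -2.99 ± 0.25 for feoB. In the wild type the signal of dksA went to 7032 ± 1837 after GSNO and 12115 ± 1561 after SNP, and in the mutant to 343 ± 69.7 and 243 ± 3.25 (SD, n = 2). The signal of feoB after SNP was 7229 ± 775 in the wild type and 636 ± 25.5 in the mutant.

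For GSNO 35 probe sets passed the test of the difference by limma, 5 higher and 30 lower in the mutant, and for SNP 32, 3 higher and 29 lower. Of these, 27 were lower with both reagents, whose tests share the untreated arrays. The median difference of all probe sets was 0.16 for GSNO, to which the values are to be compared. Without the wild type GSNO replicate 2 array 121 passed (44 higher, 77 lower), and without the mutant GSNO replicate 2 array 83 (9 higher, 74 lower). The counts of higher probe sets moved too: that for GSNO was 0 when scaled to the thrC control and 2 to 44 without single arrays, and that for SNP was 8 without the dimmest 25% of probe sets and 0 without the wild type SNP replicate 1 array. The call of feoB with GSNO was lost without the untreated wild type replicate 1 array (adjusted p 0.0653) or the untreated mutant replicate 2 array.

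Several lists differed between the strains by camera, though 0 of their members other than hemN passed alone. For GSNO ribosomal proteins had a median difference of -1.53 (adjusted p 5.5e-25, 27 lower adjusted over the list alone, and 22 past the threshold without the wild type GSNO replicate 2 array), the tricarboxylic acid cycle -0.79 and NADH dehydrogenase -0.37 (adjusted p 0.0116 for both, 2 and 0 lower adjusted over the list alone). With an estimated correlation adjusted p = 0.621, adjusted p = 0.528 and adjusted p = 0.740. For SNP bacteriochlorophyll synthesis had a median difference of -0.98 (adjusted p 2.7e-10), photosynthetic complexes -0.59 (0.00015) and heme synthesis -0.48 (7.4e-05), with 3, 0 and 2 genes lower adjusted over the list alone. With an estimated correlation adjusted p = 0.424, adjusted p = 0.695 and adjusted p = 0.424.

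**Figure D2:**
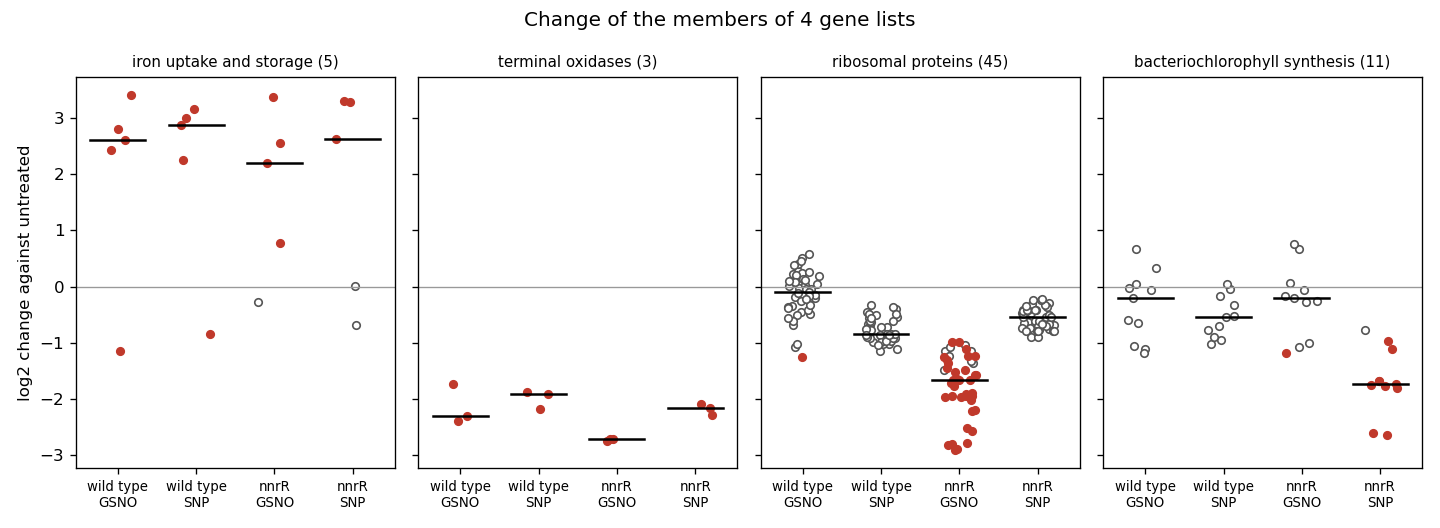
Log2 change against untreated (vertical axis) of each member of 4 gene lists, with the number of genes in brackets, for both reagents in both strains; filled points passed adjusted p 0.05, open points did not, and lines are medians. Ribosomal protein genes have a median of -1.65 with GSNO in the mutant and bacteriochlorophyll genes -1.73 with SNP in the mutant.

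The reagents were compared directly within each strain at the same dose and time. In the wild type cysT was higher with SNP by 5.47 ± 0.33 on the log2 scale and cysW by 4.48 ± 0.26, and in the mutant by 5.59 ± 0.33 and 4.83 ± 0.26. The gene hemT was higher with SNP in both strains, and its mean signals with GSNO, 27.4 ± 4.46 and 17.8 ± 4.81 (SD, n = 2), were around the pseudocount. The reverse held for metF, with differences of -4.09 ± 0.18 and -4.28 ± 0.18, for metK (-1.96 ± 0.22 and -1.94 ± 0.22), lexA (-1.75 ± 0.21 and -1.39 ± 0.21) and recA (-1.48 ± 0.23 and -1.67 ± 0.23). In the wild type metZ (-2.24 ± 0.27), cobW, of cobalamin synthesis (-1.55 ± 0.23), and rpoZ, the RNA polymerase omega subunit (-1.38 ± 0.20), were lower with SNP. In the mutant bchJ and bchE differed by -3.36 ± 0.32 and -3.32 ± 0.32, 4 probe sets of appA by -2.70 to -3.24, and hemA by -2.69 ± 0.27, all lower with SNP. Of the 45 ribosomal protein genes 14 were higher with SNP in the mutant (23 adjusted over the list alone), with adjusted p 6.4e-10 and adjusted p = 0.490 with an estimated correlation, and in the wild type 0 passed (0 adjusted over the list alone, 16 lower without the GSNO replicate 2 array) with a median of -0.65, adjusted p 6.3e-09 and adjusted p = 0.977 with an estimated correlation. Of 11 bacteriochlorophyll genes 6 were lower in the mutant (7 adjusted over the list alone), with adjusted p 2.8e-06 and adjusted p = 0.490 with an estimated correlation. Of 7 genes of the photosynthetic complexes 4 were lower with SNP in the mutant (6 adjusted over the list alone), with adjusted p 0.000213, and of 4 carotenoid genes 2 were lower (2 adjusted over the list alone), with adjusted p 0.0242. Of 9 genes of NADH dehydrogenase 3 were higher (7 adjusted over the list alone), with adjusted p 0.00759, and for these 3 lists adjusted p = 0.490 with an estimated correlation. Without the mutant array of GSNO replicate 1 or of SNP replicate 1 the 3 lists had 2, 1 and 0 members past the threshold, and without that of SNP replicate 2 they had 4, 1 and 0.

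In total 271 probe sets passed in the wild type, 181 higher with SNP and 90 lower, and 892 in the mutant, 517 higher and 375 lower. Without an array the wild type count was 166 (GSNO replicate 1), 119 (SNP replicate 1) or 102 (SNP replicate 2), and the mutant count 358 (GSNO replicate 1), 337 (SNP replicate 1) or 474 (SNP replicate 2). In the mutant 1 ribosomal protein gene passed without the GSNO replicate 1 array and 2 without either SNP array. When scaled to the thrC control the mutant balance was 1162 higher and 146 lower, and after median centring 412 and 496.

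In the wild type 83 probe sets rose and 24 fell with both reagents, and in the mutant 85 rose and 38 fell. Both responses of a strain share its untreated arrays, so no count expected under independence is given for them. In the wild type 11 probe sets and in the mutant 31 moved in opposite directions, cysT and cysW among them. Across probe sets the log2 changes with both reagents correlated with r = 0.595 in the wild type and 0.361 in the mutant. Simulated unchanged groups with shared untreated arrays gave 0.501 and 0.497. True changes add variance that the simulated groups lack, so the observed and simulated r cannot be compared, and the covariances are compared instead. The covariances were 0.266 and 0.179, against simulated 0.0469 and 0.0462 from the shared arrays alone. Between the strains, which share no array, 159 probe sets rose and 124 fell with GSNO in both, where independent lists would share 17.2 and 24.7, and 84 and 21 with SNP, against 3.96 and 0.802.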

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

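The tests of scaling, single arrays, untreated levels, the strain difference of the ribosomal list and the numbering were chosen only after the result was seen, as was scaling to the thrC control; the test of matched lists was not. Results are listed here because the effect of a reagent differed between the strains by a test of the difference itself.

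With GSNO 35 probe sets and with SNP 32 differed between the strains. Among genes with a symbol, the differences of the mutant from the wild type were -4.02 with GSNO and -5.27 with SNP for dksA, -2.77 and -4.84 for hemN, and -1.64 and -2.99 for feoB. For gene lists the median differences with GSNO were -1.53 for ribosomal proteins, -0.79 for the tricarboxylic acid cycle and -0.37 for NADH dehydrogenase. With SNP they were -0.98 for bacteriochlorophyll synthesis, -0.59 for photosynthetic complexes and -0.48 for heme synthesis. No list difference passed with an estimated correlation.

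The first pattern weighed is that feoB, hemN and dksA had lower responses in the mutant, that is, lower log2 changes. The mean signal of hemN rose in the wild type from 5596.7 to 9807.9 with GSNO and 12988.8 with SNP. In the mutant it fell from 5800.3 to 1487.3 and 456.9. The call of hemN with GSNO in the wild type was lost without single arrays and with the replicate number as a block. The mean signal of dksA was likewise higher after both reagents in the wild type, and it fell in the mutant. With GSNO in the wild type the dksA arrays read 5733.1 and 8331.5, against 3152 and 4330.8 untreated, and no call is given for this rise. The signal of feoB rose less in the mutant with GSNO, and its change there with SNP did not pass. Scaling of the arrays is argued against, since over 3 scalings the least negative of the 6 differences was -1.56, with adjusted p up to 0.0259. One deviating array is argued against as the whole cause, since the least negative of 72 differences in fits without an array was -1.55, although 2 of these, both for feoB with GSNO, had adjusted p over 0.05. A level difference before the reagents is argued against by its size, at most -0.47 ± 0.18, for feoB. That the loss of nnrR changes these responses may be put as a hypothesis, not tested further, since there is 1 mutant strain.

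The second pattern is that ribosomal protein genes fell after GSNO in the mutant. Their median was -1.58 or lower under 3 scalings and -1.29 or lower without any array, though the number of genes past the threshold went down to 8. A fall of all abundant transcripts is argued against by random lists matched on untreated signal, whose medians had a median of 0.20. Of 10000 such lists 0 had a median as low as -1.65, and the lowest was -0.59. The lists were drawn without regard to genes that vary together, so this count does not measure chance. Whether the strains differed in this fall could not be told. The median difference was -1.53, and camera with an estimated correlation gave adjusted p = 0.621. With that correlation no list passed in any contrast, and the mutant's fall itself had adjusted p = 0.291. Adjusted over the list alone, part of the genes did have a lower response in the mutant, as counted above.

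The third pattern is that many probe sets with lower responses in the mutant have consecutive numbers. In some a rise was missing from the mutant. With GSNO probe set 1204 went from 191 to 8172.9 in the wild type and from 167.9 to 158.6 in the mutant. In others the signal fell in the mutant. With GSNO probe set 2158 went from 884.2 to 90.8 there, and from 903.2 to 2125.6 in the wild type. Such probe sets numbered 30 with GSNO and 29 with SNP, and 27 were in both sets. Of those lower with either reagent, 23 lie in runs of consecutive numbers and 21 of these have no symbol. The others are hemN and feoB, so this pattern and the first overlap. For probe set 1354, also in these runs, the untreated strains already differed by 1.47 ± 0.18 (adjusted p 0.0696 by limma). A level difference before the reagents stays open for it. Placement at random in the numbering is argued against: with 17 neighbouring pairs for GSNO, 0 of 10000 random draws held as many, and the highest held 3. Lists from other comparisons were not set against such draws. The runs are therefore not shown to be particular to the strain difference. A numbering unrelated to gene order is argued against, since 132 of 137 pairs of named probe sets with consecutive numbers (96.3%) belong to genes within 2 places of each other in the RefSeq order. Each gene entered this check with 1 probe set, so whether a run holds several probe sets of 1 gene was not checked. That neighbouring genes, or several probe sets of 1 gene, share the strain difference may be put as a hypothesis. The genes without a symbol were not identified.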

How the results depend on the processing

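Scaling to the thrC control was added after seeing the data; the other alternatives were planned. The cause was not tested for any change below, except that only the arrays of the groups compared means fewer arrays for the spread. Probe sets past the threshold with only the arrays compared were 218 for GSNO in the wild type, 461 for GSNO in the mutant and 93 for SNP against GSNO in the wild type. When scaled to the control, GSNO in the wild type had 312 and SNP against GSNO in the wild type 170. The untreated strains differed for 1 probe set after quantile normalization and 1 after median centring. With an estimated correlation 0 gene lists passed in each of the 9 contrasts, and with the replicate block within genotype 1 list differed between the untreated strains.

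Without each array in turn the counts ranged from 244 to 470 (GSNO, wild type), 120 to 179 (SNP, wild type), 388 to 1083 (GSNO, mutant), 116 to 295 (SNP, mutant), 28 to 121 and 28 to 35 (differences between the strains with GSNO and SNP), 102 to 283 (SNP against GSNO, wild type), 337 to 1012 (the same, mutant) and 0 for the untreated strains. A lone remaining array was assumed to vary like the other groups. The labels do not say that a replicate number marks a shared culture or day. Deviations of same-numbered arrays from the group means correlated by -0.161 to 0.236 over 15 pairs of groups, with 7 over 0.1, and 4 of the 6 pairs within a strain over 0.1. All 3 pairs of groups within the wild type were over 0.1 (0.236, 0.159 and 0.225), and those of the mutant were not all. As not every pair was over 0.1, the fits without the block were kept, and whether the wild type numbers mark shared cultures is left open. With the number as a block, across or within strains, no total count moved by over 1.5 times (GSNO in the wild type, 528 and 497).

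Of 201 results on 90 named probe sets, 0 reversed under the alternatives run. These results were chosen past the threshold, part of them with arrays that did not overlap between groups. For that part a fit without 1 array cannot change the sign, so the lack of reversals there was fixed by the choice. Without the dimmest 25% of probe sets 197 could be compared. Calls were lost for 43 with only the arrays compared, 28 when scaled to the control, 16 without a pseudocount, 11 after median centring, 7 after quantile normalization, and 73 in at least 1 fit without an array. With the replicate number as a block adjusted p was over the threshold for 8 within strains and 7 across them, which include hemN (GSNO) and phoU and bfr of probe set 4296 (SNP) in the wild type under both blocks, and fliE (SNP, wild type) within strains. Probe sets with signals near the pseudocount of 23.8 limit what can be seen.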

Other observations

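The genes in this part were chosen after their values were seen, and no test was added for them. The regulator gene fnrL, for the anaerobic activator FnrL, rose on all 5 of its probe sets with GSNO in both strains, by 1.07 to 1.48 on the log2 scale in the wild type and by 2.22 to 2.38 in the mutant; the difference between the strains did not pass. With SNP it rose on 5 probe sets in the mutant, by 1.07 to 1.23, and on 1 in the wild type. The antirepressor gene appA rose on 5 probe sets with GSNO in the mutant, by 1.87 to 2.26, and its target in regulation, the repressor gene ppsR, had values of -0.54 to -0.97 on 5 probe sets with GSNO in the wild type, 3 of them past the threshold.

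Further genes with a symbol moved under 1 condition or more. The glycerol 3-phosphate uptake genes ugpA and ugpB rose with SNP in the wild type, by 1.46 ± 0.26 and 1.61 ± 0.23, and ugpE rose in the mutant with SNP by 1.53 ± 0.23. With GSNO in the mutant tsf, for an elongation factor, changed by -2.24 ± 0.50 and SecD, of protein export, by -1.70 ± 0.28, while ald, for alanine dehydrogenase, rose by 1.85 ± 0.32. With GSNO in the wild type nusA, of transcription termination, rose by 1.20 ± 0.26 and phoB, of phosphate regulation, changed by -1.08 ± 0.28.

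Probe set 1208, which has no symbol, had a mean signal of 29.8 in the untreated wild type, 21655 with GSNO and 22612 with SNP, and 12.2, 13.5 and 37.9 in the mutant. The low values are near the pseudocount of 23.8 and the high ones near the highest signal of an array, so no size of the difference is given. Of the 10 largest rises over all probe sets with GSNO in the wild type 0 had a symbol.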
